A study of Mus musculus with 3 samples.

How the data were processed

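The data are RNA sequencing libraries of mouse T-helper 1 (Th1) cells, a class of CD4 helper T cell. The labels call them primary cells of the C57BL/6NJ strain and link a protocol named for CD4+ T cell differentiation. The series holds 3 libraries, which the labels number as biological replicates 1, 2 and 3 of 1 cell type. All 3 form 1 group, so no group could be set against another. The labels give each library its own biosample and the same donor entry. Nothing in them says whether the cultures came from separate animals. P-values of tests between replicates therefore refer only to these 3 samples, and part of their spread may be technical. The permutation tests between gene lists use the mean of the 3 libraries and do not measure that spread.

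The deposited values are raw counts per gene. Per the file headers, read pairs were aligned in a stranded paired-end mode with an alignment step named star2, and were counted over exons with featureCounts version 1.4.6-p4. The counting used GENCODE vM13 gene models on mm10, required both reads of a pair to be aligned, and used strand setting 1, which counts a pair towards a gene when its first read lies on the gene's own strand. No further normalization of the counts is stated per the file headers. The labels call the assay total RNA-seq, while the library protocol they link is named for poly(A)+ RNA. The headers also name a time point of 2 hours, which the labels do not give.

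The tests, gene lists and naming rule were fixed before the data were examined. They assumed estimated counts and TPM values made by the authors. The deposited files hold whole counts instead. TPM was therefore computed here, from the deposited counts and the exon length that the files give for each gene, and counts entered the count models unrounded. Alternatives that needed posterior mean values were not run. CPM, the count scaled by the library's total, was computed from the same counts as an alternative without length correction. The tables hold 50600 genes, all of which entered the computation of TPM. Symbols and biotypes came from a later GENCODE release of the same assembly, matched by gene identifier without version, which named 50376 genes (99.56%). Coordinates are those of the files, on mm10.

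Total counts were 4442901 in replicate 1, 3123869 in replicate 2 and 2950658 in replicate 3. A gene with 0 counts may, at the usual limit of 3 counts, lie at up to 0.675, 0.96 and 1.02 CPM in replicates 1, 2 and 3. Intervals are 95% intervals (exact Clopper-Pearson unless Wilson is named), and intervals and floors cover counting error only.

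Each gene was also classed by its neighbours in the files' own coordinates with bedtools 2.31.1. A gene was called opposed when an exon of it overlapped an exon of a gene on the other strand, and unopposed when its whole span overlapped no gene of the other strand. Values of opposed genes are uncertain, since reads of the pair share a position and are told apart by strand alone. Values of unopposed genes are free of that uncertainty only. A strand setting opposite to the library would affect them as well. For pairs of a long noncoding RNA (lncRNA) gene and a protein-coding gene, at least 0.5 of the lncRNA's exons had to lie in the overlap, and the summed count of the pair had to reach 30. These classes and pairs, and the ribosomal protein genes among the list deviations, were added after the counts had been seen.

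Spread between replicates was modelled in edgeR 4.0.16 under R 4.3.3 with TMM scaling, an intercept-only design and the filter filterByExpr at a minimum count of 10, which kept 9469 genes. The biological coefficient of variation (BCV) is the square root of edgeR's common dispersion. Counting noise was tested per gene by a chi-square test with 2 degrees of freedom. Genes beyond the dispersion trend were found from the edgeR deviance at the trended dispersion, against a chi-square distribution with 2 degrees of freedom. Both were adjusted by Benjamini-Hochberg at 0.05, and both are one-sided. DESeq2 1.42.0 served as the alternative tool. On simulated counts for the same 9469 genes, the trend test recovered 36% of genes changed 4-fold in 1 library and 95% of those changed 8-fold, with 3 false calls. The counting noise test recovered 50% of 1.5-fold and 89% of 2-fold changes.

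The gene lists, 29 in all, held 392 entries, of which 387 were matched. A list's level is the median TPM of its members, set against 10000 random lists of protein-coding genes of the same size. The Th1 list was compared with 5 other lists on the scale log2(TPM + 0.1), leaving out shared genes, by permuting genes between the 2 lists 100000 times, two-sided, with Benjamini-Hochberg adjustment over the 5. Genes are not independent replicates, so these p-values describe the lists in these libraries. In 200 simulations with lists of 18 and 14 genes that test passed 5.0% of the time with no difference and 85.5% of the time at a log2 difference of 4. For 12 pairs of genes the log2 ratio was taken within each library. An exact sign-flip test over 3 libraries cannot go below p = 0.25. Each list's deviation in a library was compared with 10000 random lists matched on mean expression. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

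The genes named in the text followed a rule. It takes every gene of the 12 pairs, up to 4 members of each list with the highest mean TPM and the 1 with the lowest, and list members beyond the dispersion trend. It also takes the 10 protein-coding genes with the highest mean TPM, the 15 genes with the smallest adjusted p in the trend test among those at 1 TPM or more, the 3 most used Trbv and Trav segments, and Xist, Ddx3y, Uty, Kdm5d, Eif2s3y and Nnt. Some genes and pairs that the rule takes are not reported here. Genes named only as lying opposite another come from the coordinates, and other genes are named with a statement that they were chosen after their values were seen. Alternatives covered scaling, the filter on low counts, the tool, thresholds, pseudocounts, the summary over genes, the unit, and each replicate left out in turn. Further alternatives, restricted to unopposed genes or scaling opposed genes apart, were added after the counts had been seen.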

Results

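RNA was measured in mouse Th1 cells, CD4 helper T cells of the kind that makes interferon-gamma in responses to intracellular pathogens. The 3 libraries, replicates 1, 2 and 3, carried 4442901, 3123869 and 2950658 counts, and 16717, 16605 and 15603 genes had at least 1 count. There was no second group. The comparisons were therefore between gene programmes within the libraries, and between the replicates. A total of 11014 genes reached 1 TPM in every library, of which 8427 were protein-coding and 5218 unopposed. For a gene of 1 kb, the floor of 3 counts equals 1.37, 1.6 and 1.77 TPM in replicates 1, 2 and 3. Short genes can therefore reach 1 TPM at or under that floor.

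The cells carried the core transcripts of CD4 T cells with alpha-beta receptors. All 18 pan-T genes reached 1 TPM in every library, with a list median of 195 ± 88.7 TPM (SD, n = 3), above every one of the random lists. Trac, the constant region of the receptor alpha chain, stood at 897 ± 467 TPM (SD, n = 3), Cd5, a receptor signal dampener, at 419 ± 191, the kinase Lck at 404 ± 154, and the adhesion receptor Cd2 at 355 ± 128. Cd3e, a chain of the CD3 complex, was lowest at 51.4 ± 17.8 TPM. Cd4 had 1234, 636 and 659 counts in replicates 1, 2 and 3, against 2, 1 and 0 for Cd8a, the coreceptor of cytotoxic T cells. The summed counts gave a Cd4 to Cd8a ratio per exon base of 760 (95% interval 260 to 3690). Cd8b1, the other CD8 chain, had 34, 16 and 10 counts, or 6.73 ± 3.36 TPM (SD, n = 3). Trbc2, of the receptor beta chain, exceeded Trdc, of the delta chain, 90.3-fold per exon base (68.1 to 122). The summed counts were 825 and 51, with Trdc opposed by Trdv5.

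The receptor repertoire was spread over many variable segments. All 22 Trbv segments had counts, with a Shannon evenness of 0.873 ± 0.009 (SD, n = 3), where 1 would be equal use. Trbv13-2 (chromosome 6, 41121396 to 41121832) took 12.95% ± 0.99 of Trbv counts, Trbv13-1 10.79% ± 2.14 and Trbv31 8.67% ± 1.93. Of 108 Trav segments 69 had counts, with an evenness of 0.813 ± 0.008. Trav14n-3 took 6.79% ± 1.86, Trav14-3 5.58% ± 0.62 and Trav9-2 4.92% ± 1.24. The closely related members of these families can share reads, so single shares are uncertain. They rest on 739, 358 and 279 Trbv counts in replicates 1, 2 and 3.

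Markers of other cell types stood far below the T cell genes. The list medians were 0.031 ± 0.054 TPM for B cells, 0.023 ± 0.041 for macrophages and neutrophils, and 0.284 ± 0.27 for dendritic cells and MHC class II (SD, n = 3), or 0.161, 0 and 0.519 over unopposed members. The NK cell, gamma-delta T cell and erythroid medians were 0 in every library, as was that of the background list of other tissues. The CD8 and cytotoxic list stood at 0.294 ± 0.267 TPM, with Prf1, the pore-forming protein of killer cells, highest at 9.34 ± 4.15. Single members were higher. In the B cell list, Cd79a, a receptor signalling chain, reached 36.4 ± 11.1 TPM and Ighm 16.6 ± 8.75, while 6 of 13 members, Cd22 among them, had no count. Csf1r, the macrophage growth factor receptor, had 157.6 ± 25.3 TPM and opposes Hmgxb3. Tyrobp, an NK and myeloid adaptor, had 8.03 ± 5.63 TPM, and Cd74, the MHC class II chaperone, 6.16 ± 0.108. Pmel, a pigment cell gene, had 455 ± 187 TPM and opposes Dgka. Alas2, of haem synthesis, had 4.53 ± 2.28 TPM and opposes Apex2. The next macrophage gene, Cd68, with no gene opposite, had 7.23 ± 1.39 TPM, and S100a9 had no count.

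**Figure D1:**
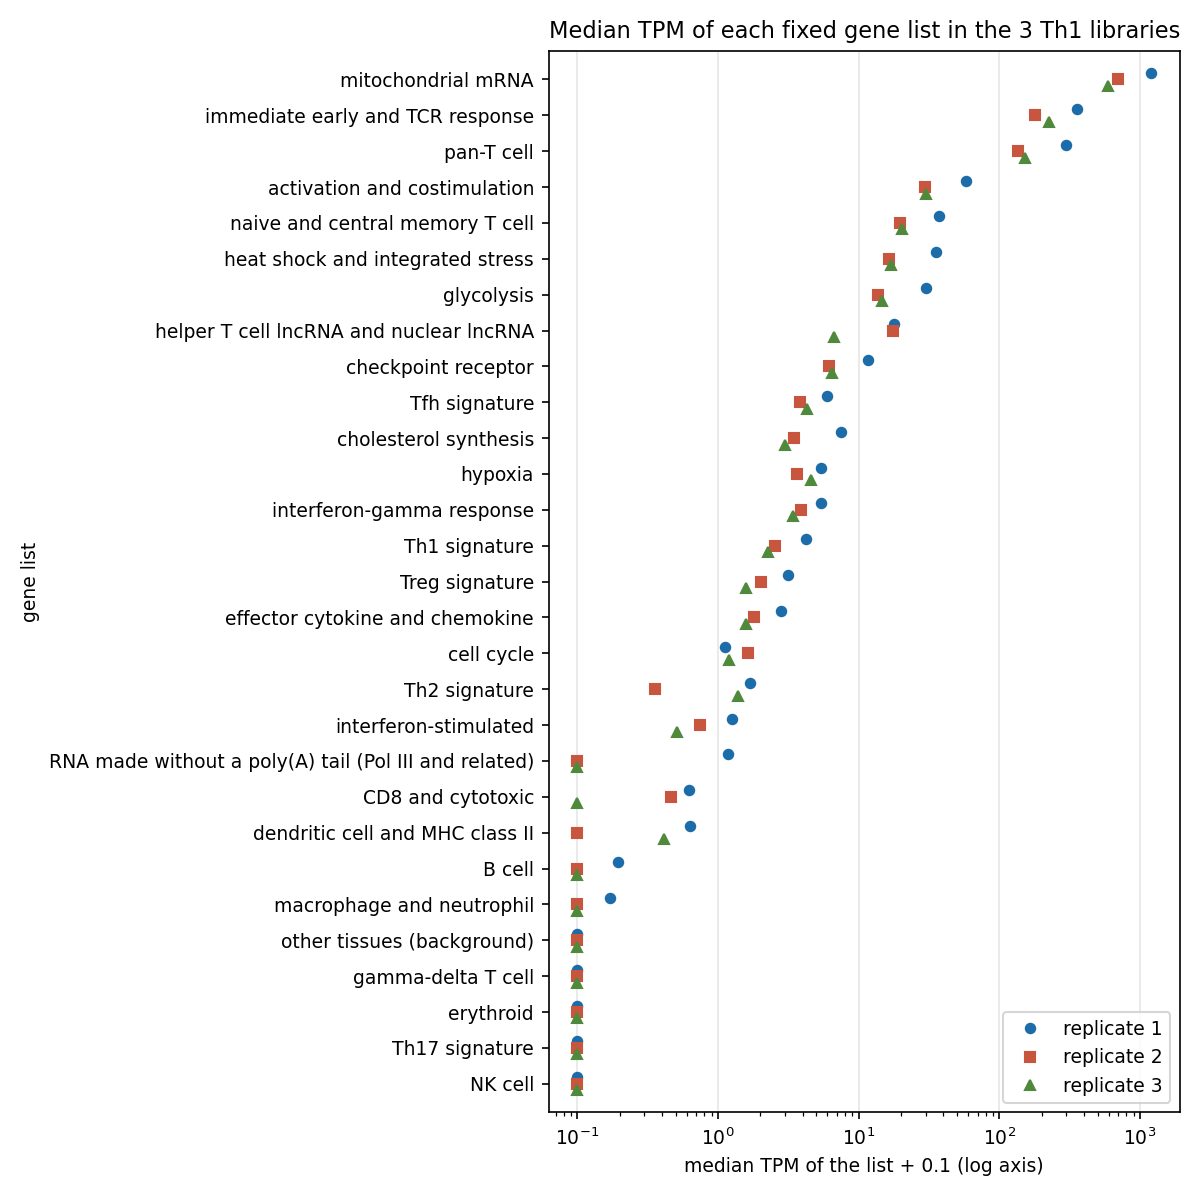
Median TPM + 0.1 of each of the 29 fixed gene lists on a log axis, with 1 symbol for each of the 3 replicates. The pan-T list sits at a mean of 195 TPM and the immediate early list at 254, while the NK cell, Th17, erythroid, gamma-delta and background lists sit at 0 in every library.

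The libraries are labelled Th1, and the comparison this implies is of the Th1 programme with those of other helper fates. With no reference cells, a difference between lists may also reflect the usual levels of their genes. It does not by itself show which programme was active. The Th1 list lay at percentiles 90.43 to 92.67 of the random lists over the 3 libraries. Lta, a cytokine of the tumour necrosis factor family, had 147 ± 41.8 TPM (SD, n = 3), the death ligand Fasl 22.99 ± 11.4, the signal transducer Stat4 15.9 ± 6.49 and the transcription factor Irf1, which Gm17334 opposes, 14.6 ± 6.05. Tbx21, the transcription factor that specifies Th1 cells (chromosome 11, 97098071 to 97115331), had 2.53 ± 0.997 TPM from 19, 7 and 11 counts. Ifng, the signature Th1 cytokine (chromosome 10, 118441046 to 118445892), had 1, 2 and 0 counts, at or under the floor of 3 counts in each library. Under a strand setting opposite to the library, a question taken up below, own reads of Tbx21, Ifng and other list genes may be lost. Such low counts would then not limit their levels. Il18rap had 2, 0 and 0 counts. Of 18 members, 10 reached 1 TPM in every library and the list median was 2.91 ± 1.05 TPM, or 0.331 over its unopposed members.

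Naive and central memory genes stood far above the Th1 list. Cd27, a costimulatory receptor, had 320 ± 109.9 TPM (SD, n = 3), Tcf7, a transcription factor of naive and memory T cells, 117 ± 53.9, the lymph node homing receptor Ccr7 99.9 ± 57.6 and the chromatin organiser Satb1 50.1 ± 17.5. All 14 members reached 1 TPM in every library, with a median of 25.6 ± 9.96 TPM, the lowest being Ly6c1 at 2.74 ± 2.13. On the log2 scale the Th1 list lay below this list by a mean difference of -3.82 ± 0.35 (SD, n = 3), negative in all 3 libraries, with an adjusted p of 0.0018 in the permutation test. Over unopposed genes, 12 against 8, the difference was -4.41 and the adjusted p of the permutation test 0.0147, the highest over 9 alternatives, of which the lowest was 0.00175.

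Among the other helper lists only the Th17 list differed from the Th1 list past the threshold. That difference, Th1 minus Th17, was 2.91 ± 0.05 (SD, n = 3; permutation test, adjusted p = 0.0169). Il17a and 6 other Th17 members had no count in any library. By counting error alone this allows Il17a up to 1.17, 1.37 and 1.51 TPM in replicates 1, 2 and 3. If the strand setting was opposite to the library, a question taken up below, its own reads may be lost and these limits would not hold. Stat3, a signal transducer used by many cytokines and opposed by Stat5a, led that list at 29.6 ± 11.6 TPM, before Rora at 1.10 ± 0.863 and Ahr at 0.305 ± 0.388, and Il17re had no count. With only genes at 0.1 TPM or more in any library the difference was 1.54 and the adjusted p of the permutation test 0.322, where the other 8 alternatives gave 0.00862 to 0.0402. The differences from the Th2, Treg and Tfh lists were 0.86 ± 0.33, -0.55 ± 0.06 and -1.20 ± 0.29, with adjusted p of 0.573, 0.634 and 0.48 in the permutation test. The Th2 difference turned to -1.74 with the same filter, and the Treg difference to 0.38 with medians in place of means.

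The Th2, Treg and Tfh lists had medians of 1.05 ± 0.703, 2.15 ± 0.792 and 4.59 ± 1.16 TPM (SD, n = 3), each with a few high members. Over unopposed members these medians were 1.05, 7.17 and 26.9 TPM. In the Th2 list, Stat6, which transmits interleukin-4 signals, had 159 ± 51.3 TPM and opposes Nab2, the chemokine receptor Ccr8 had 42.98 ± 7.36, Ptgdr2, opposed by Ccdc86, 23.9 ± 5.52 and Gata3, the Th2 master regulator, 5.28 ± 1.86, while Il31 had no count. In the Treg list, Foxp3, the regulatory T cell factor, had 59.6 ± 6.85 TPM and opposes Ccdc22, Il2ra had 44.5 ± 21.1, Izumo1r 35.2 ± 3.58 and Tnfrsf18, opposed by Gm16008, 34.1 ± 7.60, while Nrp1 had 0.0493 ± 0.0469. In the Tfh list, the inhibitory receptor Btla had 71.9 ± 34.7 TPM, Pdcd1 50.2 ± 15.3, Bcl6 31.3 ± 11.2 and the costimulator Icos 29.04 ± 13.6, while Cebpa had no count. Il4, the Th2 cytokine, had 5, 1 and 5 counts, and Il10 had 1, 2 and 1.

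**Figure D2:**
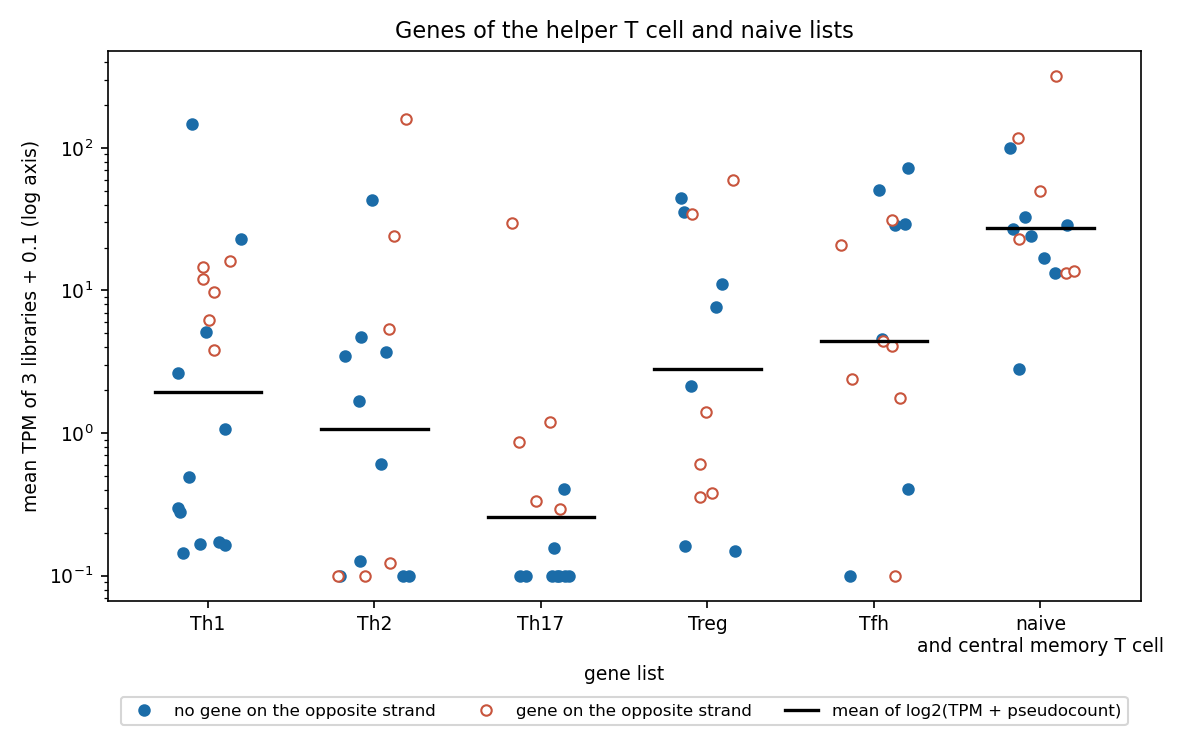
Mean TPM of 3 libraries + 0.1 for each gene of the Th1, Th2, Th17, Treg, Tfh and naive lists on a log axis, with open symbols for genes whose span overlaps a gene on the opposite strand and a black line at the mean on the log2 scale. The 14 naive genes all lie above 1 TPM, while 10 of the 18 Th1 genes reach 1 TPM in every library.

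Ratios of lineage genes within each library had 1 sign in all 3 libraries for every pair below except Ifng to Il4, each with p = 0.25 in the exact two-sided sign-flip test, the smallest that 3 libraries allow. The log2 ratio of Tbx21 to Gata3 was -1.05 ± 0.21 (SD, n = 3), to Bcl6 -3.60 ± 0.33 and to Foxp3 -4.57 ± 0.57. Tbx21 lay above Eomes, a related factor of cytotoxic cells, by 1.25 ± 0.54. Gata3, Bcl6, Foxp3 and Eomes are all opposed by a gene on the other strand, and Tbx21 is not. Il12rb2, a receptor chain for the Th1-inducing cytokine, lay below Il4ra at -2.65 ± 1.10, with both opposed. The log2 ratio of Cxcr3 to Ccr4, chemokine receptors of Th1 and Th2 cells, was 1.5 ± 1.30, but their summed counts were 10 and 10, and the ratio per exon base of 1.79 had an interval of 0.667 to 4.78. Ifng to Il4 rested on 3 and 11 summed counts, a ratio of 0.258 (0.0463 to 0.978), with the sign shared by 2 of 3 libraries. No ratio was formed for Ifng to Il17a or Il10, since every count was at or under 3.

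Genes of recent T cell receptor signalling were among the highest of all. All 14 immediate early genes reached 1 TPM in every library, with a median of 254 ± 92.6 TPM (SD, n = 3), above every one of the random lists. Nr4a1, an orphan nuclear receptor induced by antigen receptor signals, had 1463 ± 603 TPM, Nr4a3 598 ± 215, the zinc finger factor Egr3 383 ± 30 and Myc 382 ± 144. Fosb was lowest at 5.41 ± 1.6. The activation list, all 13 of whose members reached 1 TPM, had a median of 39.4 ± 16.3. It was led by Cd40lg, the helper ligand for B cells, at 859 ± 290.3, Irf4 at 175 ± 75.4, Slc3a2 at 71.3 ± 25.6 and Slc7a5 at 63.2 ± 34.1, the last pair forming an amino acid transporter. Cd44 was lowest at 4.63 ± 3.08.

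Effector cytokines ranged from high levels to no count. Tnf stood at 516 ± 163 TPM (SD, n = 3), Ltb at 230.0 ± 73.3, Lta at 147 ± 41.8 and Tnfsf11, the ligand RANKL, at 98.9 ± 33.03. Il2, the T cell growth factor, chosen after its values were seen and overlapped by a gene of the other strand, had 28.6 ± 18.7 TPM from 123, 27 and 47 counts. The list median was 1.95 ± 0.65 TPM, or 1.19 over unopposed members, 8 of 17 members reached 1 TPM in every library, and Ccl1 had no count. In the glycolysis list (median 19.4 ± 9.31 TPM) Ldha, lactate dehydrogenase, had 203 ± 104 TPM, Aldoa and Gapdh, both opposed, 77.1 ± 35.4 and 74.9 ± 38.8, and Pkm 63.6 ± 27.1, and Hk2 was lowest at 1.32 ± 0.531. Cell cycle genes had a median of 1.22 ± 0.283 TPM, or 0.574 over unopposed members, at percentiles 69.5, 85.98 and 79.98 of random lists in replicates 1, 2 and 3. Pcna, the replication clamp, had 123 ± 50.9, Ccna2, which opposes Exosc9, 56.7 ± 10.8, and the replication licensing factors Mcm4 and Mcm6 20.6 ± 9.07 and 18.8 ± 8.30. The mitotic kinase Aurkb had no count.

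The genes with the most counts lay largely opposite other abundant genes. The 8189 opposed genes (16.18% of all genes) held 55.1%, 69.1% and 67.3% of counts in replicates 1, 2 and 3, a mean of 63.8% ± 7.64 (SD, n = 3), and 75.3% of TPM. Unopposed genes, 70.09% of all genes, held 30.7% ± 7.03. The 95% Wilson intervals of all shares of counts given here for a single library reach at most 0.054 percentage points to either side. Among 235 pairs of a lncRNA and a protein-coding gene with opposed exons, the lncRNA had the higher count per base in 211 (89.8%, exact interval 85.2 to 93.3), with a median 27.1-fold difference. Across pairs, which are not independent replicates, both counts rose together (Spearman's rho 0.584, Pearson's r 0.506 on log2 counts per base).

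Several of the genes behind this were chosen after their values were seen. Gm26669 (chromosome 12, 80108034 to 80113000) had 55418, 66994 and 61720 counts in replicates 1, 2 and 3. Zfp36l1, an mRNA decay factor on the other strand (80107754 to 80113013), had 3120, 1520 and 1307. Kdm6bos and the histone demethylase gene Kdm6b on its other strand had means of 11440 ± 2702 and 368.5 ± 86.1 TPM. Phykpl had 27810, 28848 and 28525 counts and Hnrnpab opposite it 3611, 1897 and 2230. Among the 10 protein-coding genes of highest TPM, Gm20721 at 6480 ± 1213 opposes Gnas, Gm17606 at 3188 ± 620 opposes Acin1 and Gm37419 at 2309 ± 956 opposes Bcl6. The others were mt-Nd6 at 29160 ± 6458 TPM, Rps24 at 3718 ± 1994, the elongation factor Eef1a1 at 3122 ± 1107, Rps15 at 2776 ± 1335, mt-Co1 at 2659 ± 1278, B2m at 2526 ± 1356 and Rpl17 at 2489 ± 849. Mitochondrial mRNAs as a list had a median of 829.9 ± 324 TPM, or 1.17 over unopposed members, with mt-Cytb at 1866 ± 872 and mt-Nd1 at 1368 ± 726. mt-Co3 had no count, and of those looked up afterwards mt-Co2, mt-Atp6 and mt-Nd4l had none, mt-Atp8 0, 0 and 1, and mt-Nd3 2, 1 and 0. mt-Nd6, which lies on the mitochondrial strand opposite to the other mRNAs, exceeded the median of the detected mRNAs of that other strand 17.2-fold, 16.97-fold and 57.4-fold per base.

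**Figure D3:**
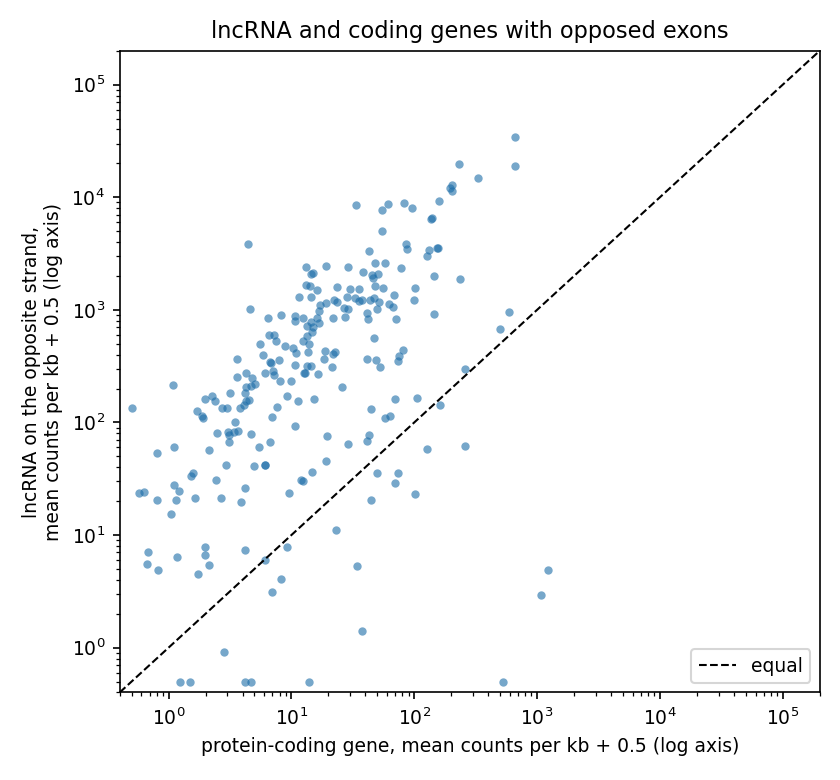
Mean counts per kb + 0.5 of 235 lncRNA genes against those of the protein-coding gene on the opposite strand, both on log axes, with a dashed line at equality. The lncRNA is the higher of the pair in 211 of the 235.

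RNA classes were examined because the labels name total RNA and the linked protocol poly(A)+ RNA. They can bear on this only if the strand setting matched the library, which is in question. Replication-dependent histone genes, whose mRNAs lack a poly(A) tail, held 0.001% ± 0.001 of counts (SD, n = 3), snRNA genes 0.034% ± 0.011 and snoRNA genes 0.032% ± 0.008. In the list of other RNAs made without a tail, Rn7sk had 9, 30 and 7 counts, Rnu11, Rpph1 and Rmrp had at most 3, and Rn7s2 had none, with a list median of 0.36 ± 0.624 TPM, or 0 over unopposed members. Nuclear rRNA genes held 2.18% ± 1.37 and were highest in replicate 2, at 3.68% against 0.993% and 1.86%. Nearly all of these rRNA counts lay on 1 gene, CT010467.1, chosen after its values were seen and opposed by Gm42418. It had 43950, 114764 and 54684 counts in replicates 1, 2 and 3. Protein-coding genes held 69.6% ± 7.89 and lncRNA genes 23.4% ± 5.12. All of these shares hold for the strand setting 1 of the deposited counts, under which reads of the other strand of a gene are not counted towards its class.

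Genes on the strand opposite Mid1 and Malat1 were among those that varied most between replicates. Gm15247 and Gm15726, both opposite Mid1, had 38, 500 and 447 and 145, 1517 and 1851 counts in replicates 1, 2 and 3 (edgeR trend test, adjusted p = 7.13e-08 and 8.85e-07), and G530011O06Rik, also opposite Mid1, 40, 190 and 203. Gm37376 and ENSMUSG00000092267, opposite the nuclear lncRNA Malat1, were highest in replicate 2, with 7222, 34678 and 8744 and 5333, 26230 and 4753 counts. Fam196b (31, 199 and 53), Tagap1 (98, 241 and 31), A830035A12Rik (44, 168 and 28), Gm42502, Gm37520, Gm15872, Gm17137 and Gm37563 were also highest in replicate 2. Gm26527 and Gm17039 were lowest in replicate 3, with 204, 168 and 15 and 102, 143 and 14 counts.

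In all, 23 of 9469 genes were beyond the dispersion trend (edgeR, Benjamini-Hochberg), 611 at an unadjusted p under 0.05, and DESeq2 marked 4 as outliers, all 4 among the 23. In 14 of the 23 the farthest library was replicate 2, always higher, and in 7 replicate 1, always lower. The count was 3 without replicate 2 and 6 without replicate 3. It was 55 among unopposed genes, of which 1, Tagap1, was among the 23. There the farthest library was replicate 1, always lower, in 44, and replicate 2 in 11, higher in 10 and lower in 1, Rps29, named after its value was seen. The BCV was 0.28, and 5642 genes differed by more than counting noise. Without replicate 1 these were 0.197 and 2476. Replicate 1 differed across the library. Of 3625 unopposed genes with at least 100 summed counts, 3446 (95.1%) were higher there than in the mean of replicates 2 and 3. These counts were taken relative to those of opposed genes, and the median difference was 1.87-fold. In the 235 pairs of a lncRNA and a coding gene, the lncRNA was higher by a median of 19.6-fold per base in replicate 1. In replicates 2 and 3 it was higher by 36.8-fold and 32.4-fold. The split of counts between the strands thus also differed in replicate 1. Whether this underlies its other differences was not tested. The pairs of libraries differed beyond counting noise in 51.5% of genes for replicates 1 and 2, 44.8% for 1 and 3 and 26% for 2 and 3, so no library was a second copy of another.

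No gene of the fixed lists was beyond the trend in the edgeR test over all genes. Of 179 list genes tested 7 had an unadjusted p under 0.05. With 0 genes called in each of the 18 lists with at least 5 tested members, Fisher's exact test of enrichment could not be informative. In the edgeR fit on unopposed genes alone Cd79a of the B cell list passed, with 86, 133 and 83 counts in replicates 1, 2 and 3 (adjusted p = 0.041). None of the 4 DESeq2 outliers was a list gene. Adjusted over the list alone, Cxcr6 of the Th1 list, named after its value was seen, and Malat1 of the lncRNA list passed. Some lists shifted as a whole. The 81 ribosomal protein genes tested had median log2 deviations of 0.35, -0.51 and 0.14 in replicates 1, 2 and 3, and 0.18, -0.39 and 0.20 over unopposed genes alone. Replicate 3 of these lay at percentile 9.81 over all genes and at 100 over unopposed genes. Cholesterol synthesis genes deviated by 0.50, -0.30 and -0.28, and by 0.29, -0.11 and -0.27 over unopposed genes, where replicate 2, at percentile 15.14, was within the central 95% of random lists. Glycolysis genes deviated by 0.26, -0.36 and 0.08, and by 0.13, -0.28 and 0.09 over unopposed genes, where replicate 1, at percentile 91.32, was within it. Activation genes deviated by 0.32, -0.24 and -0.07. Over unopposed genes their replicate 1 lay at percentile 98.15, and replicate 2, at 9.06, was within the central 95%. Pan-T genes deviated by 0.24, -0.19 and 0.01, with every replicate within the central 95% over unopposed genes. Mitochondrial mRNAs deviated by 0.19, 0.04 and -0.34 (percentiles 98.72, 31.14 and 0) and the lncRNA list by 0.38, -0.10 and -0.36 (99.88, 24.16 and 0), with under 5 unopposed genes tested in each. Immediate early genes in replicate 2, at -0.19, and Tfh genes in replicate 3, at -0.19, were also outside over all genes and not over unopposed genes. The ribosomal protein, cholesterol and glycolysis groups had the same signs with DESeq2 size factors and with opposed genes scaled apart. Of 57 combinations of list and library 17 lay outside the central 95% of matched random lists, where chance gives 2.9. Over unopposed genes 7 of 33 did. Opposed genes as a class had a median deviation of -0.28, 0.13 and 0.14 and the remaining genes 0.15, -0.08 and -0.03.

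Transcripts of the sex chromosomes differed between the libraries. Xist, the RNA that coats the inactive X chromosome of females, had 614, 810 and 1 counts in replicates 1, 2 and 3. Tsix, its opposing transcript, chosen after its values were seen, had 438, 3966 and 4. The Y genes Ddx3y, Uty, Kdm5d and Eif2s3y together had 822, 1 and 567 counts, or 185, 0.32 and 192 CPM. Replicate 1 thus had both sets, replicate 2 the X set and 1 count of the Y set, and replicate 3 the Y set and 5 counts of the X set. The labels record no sex. Nnt, a mitochondrial enzyme gene that is truncated in some C57BL/6 substrains, had 28, 13 and 13 counts, or 1.30 ± 0.454 TPM (SD, n = 3).

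**Figure D4:**
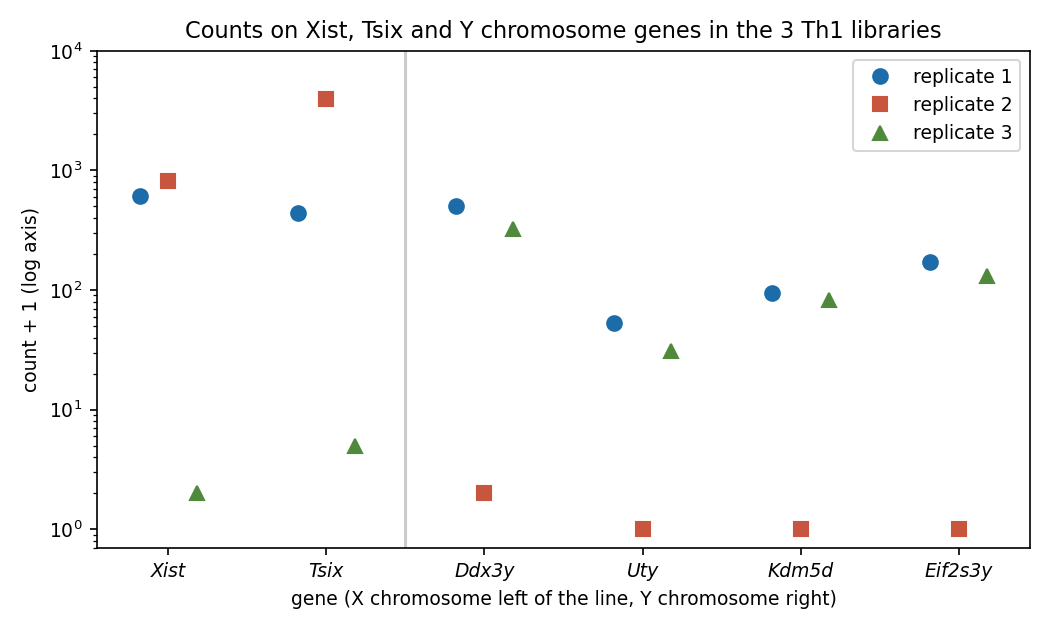
Counts + 1 of Xist, Tsix and the Y chromosome genes Ddx3y, Uty, Kdm5d and Eif2s3y on a log axis, with 1 symbol for each of the 3 replicates. Replicate 2 has 1 count over the 4 Y genes, and replicate 3 has 1 count of Xist and 4 of Tsix.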

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

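Alternatives restricted to unopposed genes, or scaling opposed genes apart, were chosen after the data had been seen, and all others before. Over all results 167 alternative values kept their side of the threshold or moved by less than the spread, 32 moved further, 1 lost its call and 2 changed sign. The comparison of the Th1 with the naive list kept its direction and its call under all 9 alternatives, as did its comparison with the Tfh list its direction. With only genes at 0.1 TPM or more, Th1 minus Th2 turned to -1.736 and Th1 minus Th17 fell short of the threshold at 1.543 (permutation test, adjusted p 0.276 and 0.322, with fewer genes tested). With medians over genes Th1 minus Treg turned to 0.376 (permutation test, adjusted p 0.886). Over their 9 alternatives the adjusted p of the permutation test ranged from 0.276 to 0.897 for Th2, 0.00862 to 0.322 for Th17 and 0.309 to 0.886 for Treg. Genes beyond the dispersion trend, 23 in the main setting, numbered 41 without the count filter, 55 among protein-coding genes, 55 among unopposed genes, 48 with separate scaling and 4 as DESeq2 outliers. Leaving out 1 replicate gave 3 to 21 such genes, a BCV of 0.197 to 0.349, 2476 to 4815 genes beyond counting noise and a histone share of 0.001% to 0.002%. Unopposed genes alone gave a BCV of 0.201, 1536 genes beyond counting noise, 5218 expressed genes and 7 list deviations, with fewer genes tested. Shares of TPM in place of counts were 75.3% for opposed and 20.3% for unopposed genes, 40.8% for protein-coding genes, 38.6% for lncRNA, 3.84% for mitochondrial mRNA, 2.92% for mt-Nd6, 0.565% for snRNA, 0.482% for snoRNA and 0.004% for histone genes, the short genes weighing more by construction. Without length correction the log2 ratio of Tbx21 was -1.73 to Gata3, -5.27 to Foxp3, -5.04 to Bcl6 and 0.58 to Eomes, and that of Trbc2 to Trdc 3.79. At a pseudocount of 1 Tbx21 to Gata3 was -0.83 and to Bcl6 -3.18, and Cd4 to Cd8a was 6.54, against 10.5 at 0.01, since Cd8a lies near 0. For other shifts the cause was not tested. Alternatives with posterior mean values were not run, since whole counts were deposited. No paired analysis was possible because the series has 1 group. With 2950658 to 4442901 counts per library, genes with 3 or fewer counts, Ifng among them, could not be ranked.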

Other observations

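The test of lncRNA and coding pairs and all values over unopposed genes were chosen after the counts had been seen, and the comparison of mt-Nd6 with the other mitochondrial mRNAs and the range of pair ratios after their own results had been seen. Inhibitory and stress genes add to the picture of the cells. The checkpoint receptor list had a median of 7.98 ± 3.13 TPM (SD, n = 3), or 2.57 over unopposed members, with Btla at 71.9 ± 34.7, Pdcd1, which encodes PD-1, at 50.2 ± 15.3, Cd160, opposed by Pdzk1, at 11.01 ± 1.83, Ctla4 at 10.9 ± 6.56 and Entpd1 at 1, 0 and 1 counts. The heat shock and integrated stress list stood at 22.9 ± 10.8 TPM, or 8.99 over unopposed members. It was led by the translation stress factor Atf4 at 274 ± 130, the chaperone Hsp90aa1 at 238 ± 63.4, Ddit3 at 101 ± 14.8, which opposes Mars, and Atf3 at 58.5 ± 28.7, while Chac1 had no count. Hypoxia genes had a median of 4.46 ± 0.885 TPM, from P4ha1 at 15.3 ± 5.77, Higd1a at 8.63 ± 2.59, Vegfa at 6.87 ± 3.69 and Ndrg1 at 6.31 ± 3.73, with Higd1a and Ndrg1 opposed, to Adm at 2, 0 and 0 counts.

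Interferon and sterol lists differed in rank among the random lists, at percentiles 56.2 to 66.73 for interferon-stimulated genes, 94.0 to 95.74 for the interferon-gamma response and 90.33 to 95.63 for cholesterol synthesis. The interferon-stimulated list had a median of 0.738 ± 0.382 TPM (SD, n = 3), or 0.472 over unopposed members, with Bst2 at 13.5 ± 9.47, Usp18 at 10.6 ± 2.24, Isg15 at 9.01 ± 4.64, Irf7 at 7.72 ± 0.593 and no count for Ifi44. Usp18 and Irf7 are opposed by other genes, as are Psmb9, Psmb8 and Cyp51. The interferon-gamma response list had a median of 4.13 ± 1.01 TPM. The feedback inhibitor Socs1 led it at 61.3 ± 29.7, followed by the immunoproteasome subunits Psmb9 at 44.7 ± 7.77 and Psmb8 at 26.4 ± 13.3 and by Igtp at 18.6 ± 6.81, and Cxcl9 had no count. Cholesterol synthesis genes had a median of 4.56 ± 2.504 TPM, with Cyp51 at 22.9 ± 14.7, Hmgcs1 at 21.9 ± 12.2, Mvd at 11.7 ± 3.67 and Dhcr7 at 0.995 ± 0.489. In the helper and nuclear lncRNA list (median 13.95 ± 6.40 TPM, or 36.4 over unopposed members) Malat1 stood at 327 ± 208, Mir155hg, the precursor of miR-155, at 77.2 ± 41.7, Gas5 at 59.96 ± 30.8 and Snhg1 at 46.2 ± 28.9, and Dnm3os had no count.

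Counts gathered on genes that lie opposite other genes. A candidate explanation is that the strand setting was opposite to the strand the library preserves, so that most reads of a gene were assigned to whatever lies across from it. The lncRNA of a pair was the higher in 89.8% of 235 pairs, where a matching setting without antisense transcripts would leave the coding gene the higher in most pairs. Abundant natural antisense transcripts in a correctly stranded count are argued against for the mitochondrial mRNAs. Per base, mt-Nd6 lay at least 16.97-fold above the median of the detected mRNAs of the other strand. It also exceeded the highest of the 12 mRNAs of that strand 6.8-fold, 11.1-fold and 20.58-fold in replicates 1, 2 and 3. For the other pairs natural antisense transcripts stay open, since mt-Nd6 is 1 gene and itself part of the pattern. Under a reversed setting the counts of unopposed genes may be the minority of reads with the reverse orientation, and the shares of histone, snRNA, snoRNA and rRNA genes would not tell total RNA from poly(A)+ RNA.

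Naive genes lay far above Th1 genes in cells labelled Th1. No reference cells were measured that would show how far apart these lists usually lie. Reads of opposite genes counted towards list genes are argued against as the whole cause, since the difference was -4.414 on the log2 scale over unopposed genes. This explanation was first worded as a reversed strand setting as such. It was narrowed after its result was known, since that setting would affect unopposed genes too. Another candidate is a loss of the genes' own reads, unequal between genes, under a reversed strand setting. The log2 ratios of the pairs had an interquartile range of 2.73. That fell short of the size of the list difference, which this cause had been predicted to reach. The range describes single pairs and not list means, and no value gives the loss per list gene. This test therefore cannot decide, and the loss stays open. A large share of cells of other types is argued against too. No B cell, macrophage or dendritic cell median exceeded 0.0021 of the pan-T median in any library. No gene of those 3 lists was shared with another list, and 2, 2 and 3 members reached 1 TPM. In the same lists 6, 6 and 5 members had no count, so the medians say little of single members. A minor share is not excluded, with Cd79a at 36.4 TPM and Ighm at 16.6, both unopposed. Unequal loss of reads would affect these lists as well. Sampling soon after activation may account for the list difference. The immediate early list lay above all random lists, at percentile 100, in each library, and the file headers name 2 hours. The pan-T, activation and mitochondrial lists also lay at percentile 100 in each library. Without reference cells this percentile alone therefore cannot decide. Naive cells that had not begun to differentiate stay open too, as no label or list separates them from cells in their first hours.

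Xist and Tsix counts differed between libraries. Source animals of different sex may account for this, since replicate 3, with 5 counts of Xist and Tsix, had 192.16 CPM on 4 Y genes, the highest of the 3 libraries, while replicate 2, with 4776, had 0.32. Replicate 1, with 1052 counts of Xist and Tsix and 185 CPM on the Y genes, would then hold cells of both sexes. No biological explanation was otherwise tested, as the labels record no sex.

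Mid1, chosen after its values were seen (X chromosome, 169685199 to 170005736), had 27, 75 and 70 counts in replicates 1, 2 and 3. Gm15247, Gm15726 and G530011O06Rik on its other strand, between 169975043 and 169986939, deviated by -3.01, -2.95 and -2.12 on the log2 scale in replicate 1. The rRNA gene CT010467.1, also chosen afterwards, had 43950, 114764 and 54684 counts, and Malat1 4120, 7315 and 1828, both highest in replicate 2.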
